A study of Homo sapiens with 6 samples.

How the data were processed

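Gene expression was measured by RNA sequencing in 6 HT-1080 libraries, 3 labelled control and 3 labelled KIF20A knockdown. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made from it with an mRNA library kit for Illumina. The labels give neither the hairpin sequence nor the number of hairpins, and no time after knockdown.

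The authors deposited raw read counts per gene for each library. Per the file headers, these were made with featureCounts 1.5.2 at default options, so that reads were counted without strand, reads mapping to several places were dropped, and the gene models were a UCSC annotation of hg38. Per the submitters' processing notes, Bowtie 0.12.2, featureCounts, Subread 1.6.5 and DESeq2 were used with hg38. The Subread version differs from that of the headers, and which aligner made the alignments is not given in the sources used here. Counting of this kind leaves genes uncertain that overlap another gene on either strand or have near-identical copies. Among the genes named, KIF20A shares exon positions with CDC23, ANLN with KIAA0895, ACTA2 with ACTA2-AS1, BCL2L1 with ABALON, MCL1 with ADAMTSL4-AS1, PLAU with C10orf55, MTOR with MTOR-AS1, ZFAS1 with ZNFX1, KCNQ1OT1 with KCNQ1, IDI1 with IDI2-AS1, COL7A1 with MIR711, LAMB3 with MIR4260, and COL5A1, SESN3 and CORO1A with unnamed loci. The deposited series table holds values on a log2 scale. Per the submitters' processing notes DESeq2 was used, and DESeq2's variance-stabilizing transformation fitted with the group (version 1.42.0) matched the table to within 5.0e-09 for 20689 of its 20715 rows matched by name. Among its names, 26 are dates, as spreadsheets make of some gene symbols, and 2 repeat. All 6 of its sample columns match a sample title.

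Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr at defaults were kept (15397 of 26485), libraries were scaled by TMM, and group differences were tested with glmQLFit (robust) and glmQLFTest with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold is its size over the square root of the F statistic. The glmTreat function tested changes against a 1.5-fold range. Levels are given as TMM-scaled CPM. Gene lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 31 tested lists, beside camera with an estimated correlation and fry. A further 6 lists, chosen after the data were seen, were tested in the same way and adjusted over these 6. They held cytosolic and mitochondrial aminoacyl-tRNA synthetases, ATF6 and XBP1 targets of the endoplasmic reticulum, heat shock, lysosome and BMP-responsive genes. Lists, tests and most alternatives were fixed before the data were examined. List symbols were matched to the older symbols of the count files through the synonyms of a RefSeq gene table. KIF20A was also tested with an exact two-sided permutation test of its log2 CPM.

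The genes named were chosen by a rule fixed beforehand. It takes KIF20A, the 12 largest rises and the 12 largest falls in log2 fold among genes at an adjusted p under 0.05 with a mean log2 CPM of 2 or more and groups that do not overlap, and from each list up to 3 members at an adjusted p under 0.05 with the smallest p. For lists with none it takes the 2 most highly expressed. Other genes named are said to be chosen after their values were seen, except that neighbouring genes and the list members KIF5B and KIF1B are named without a value.

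With 39676357 to 44850154 counts per library, counting error is small for most tested genes. Counts of replicate pairs differed by more than Poisson noise, with a chi-square per degree of freedom of 3.07 to 11.5 within groups and 182 to 223 between groups, so that no library was a copy of another. The procedure was tested on simulated data drawn from these libraries' means and dispersions, with 100 genes changed by 1.5-fold and 100 by 2-fold among 15236 in the fit. A small further list was raised as a set. The procedure recovered 77% and 87% of the changed genes, and 4.88% of its calls were false. Few genes changed in the simulation, while 66.9% of tested genes changed in the real libraries. Its false share therefore cannot be carried over to the real calls. When a trend on coding length was added to simulated libraries, 4865 false calls arose, and 13 (6.37% of calls) after removal of the coding length and A content trend.

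Coding length, base content and 3' UTR length came from the longest coding transcript per gene of GENCODE release 29, matched by symbol, and 87.6% of the tested genes had a coding sequence. The trend was removed with loess (span 0.3) of each library's deviation from the gene mean on log2 coding length and coding A content, used as offsets in edgeR. A second version used transcript length and GC content.

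The alternatives were DESeq2 size factors, total counts and upper-quartile factors for TMM, no count filter and a mean of 1 CPM, edgeR without robust estimation, DESeq2's Wald test, limma-voom, a threshold of 0.01, protein-coding genes only, treat ranges of 1.2-fold and 2-fold, the replicate number as a block, each library left out in turn, and the 2 trend removals, which were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Mitochondrially encoded genes are absent from the count files and were not tested.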

Results

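Gene expression was compared between HT-1080 cells, an established human fibrosarcoma line, with and without knockdown of KIF20A. The title of the series names PI3K-AKT signalling. KIF20A is a kinesin motor that works at the central spindle during cytokinesis. The labels divide 6 libraries into 3 controls and 3 with KIF20A knockdown. The series calls them cell lines, but nothing states whether the 3 libraries of a group came from separately made cultures, so p-values measure the spread between these libraries. Gene counts summed to 40485018, 39676357 and 44850154 in control replicates 1 to 3 and to 44097391, 43728483 and 40746514 in knockdown replicates 1 to 3. Counts were above 0 for 17973 to 18409 of 26485 listed genes per library.

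KIF20A was lower in all 3 libraries labelled knockdown than in all 3 labelled control. Its counts were 4188, 4241 and 4547 in control replicates 1 to 3 and 2344, 2334 and 2235 in knockdown replicates 1 to 3. Scaled to library size, the level was 101 ± 3.07 CPM (SD, n = 3) in the controls and 55.3 ± 1.25 CPM (SD, n = 3) in the knockdown libraries, which is 54.6% of the control level. The log2 fold change was -0.87 with a standard error of 0.051, and edgeR's quasi-likelihood test gave an adjusted p of 6.9e-16. The exact two-sided permutation test gave p = 0.10, the smallest value that 3 libraries against 3 allow. The gene lies on chromosome 5 from 138178728 to 138187715 of hg38, plus strand, with 19 exon blocks in the counting annotation, some of which overlap exons of CDC23, so a share of the reads of that stretch is uncertain. The level goes with the sample labels and against the command lines in the headers of the count files. There the output named for each of the 3 control samples carries the name of a KIF20A short hairpin, and that for each of the 3 knockdown samples the name of a control hairpin. Mitosis genes fell as well, with KIF20A at percentile 52.5 of their log2 folds, so its level may not show which construct a library carried. Groups are called by their labels below, and every direction is that of libraries labelled knockdown relative to libraries labelled control. The 6 outputs lay in 2 folders, 1 per group, so that a processing batch and the group cannot be told apart.

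**Figure D1:**
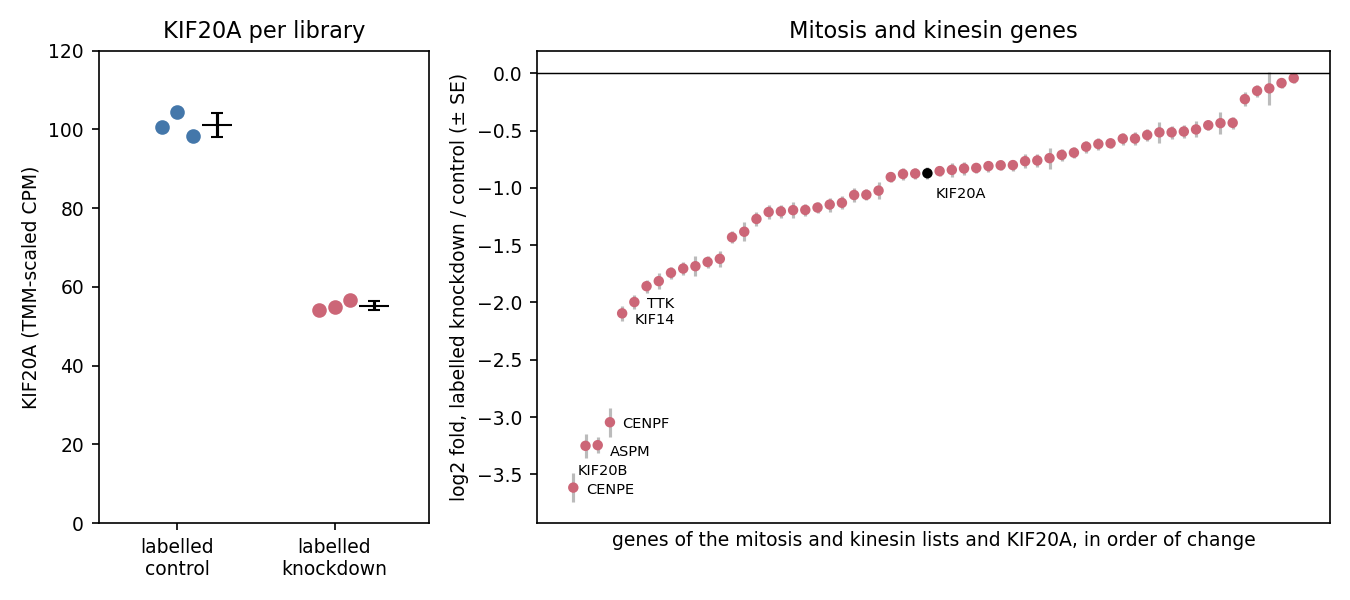
KIF20A in CPM (TMM-scaled) in each of the 6 libraries, with mean and SD beside the points (left), and the log2 fold change, labelled knockdown over labelled control, of each gene of the mitosis and kinesin lists and KIF20A, with its SE (right). The controls lie at 101 ± 3.07 and the knockdown libraries at 55.3 ± 1.25 CPM, and KIF20A sits in the middle of the mitosis genes.

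Most expressed genes differed between the groups. Of 15397 genes tested, 10307 (66.9%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5163 higher and 5144 lower in the libraries labelled knockdown. The groups did not overlap in 10737 genes (69.7% of those tested, against 10% by chance for 3 against 3). The first principal component, which separated the groups, held 94.4% of the variance over 10328 genes. Changes were mostly moderate, since 1787 genes had a fitted fold of 2 or more, 746 higher and 1041 lower, and 2529 exceeded a 1.5-fold range by edgeR's treat test, 1138 higher and 1391 lower. This count was 6474 against a 1.2-fold range and 715 against a 2-fold range. Such a count rests on a small spread, a biological coefficient of variation of 5.28%.

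Among genes with a mean log2 CPM of 2 or more and groups that do not overlap, the 12 largest rises included several genes of the amino acid stress response. CHAC1, which degrades glutathione, rose 59.0-fold, from 1.15 ± 0.32 to 68.6 ± 2.37 CPM (SD, n = 3 each; log2 fold 5.88, SE 0.10, edgeR adjusted p = 2.8e-29). INHBE, an inhibin beta subunit, rose 42.7-fold and ADM2, a peptide of the adrenomedullin family, 30.1-fold. The asparagine synthetase gene ASNS rose 9.89-fold and the pseudokinase gene TRIB3 8.40-fold. C5AR1, the complement C5a receptor, rose 42.8-fold from a control mean of 0.253 CPM, and MYCT1 14.4-fold from 0.545 CPM. The transcription factor genes EGR1, KLF4 and JDP2 had log2 folds of 4.12, 3.59 and 3.38, and ESM1 and RAB39B of 3.44 and 3.39. Among the 12 largest falls CENPE, a kinetochore kinesin, fell from 140 ± 6.35 to 11.4 ± 2.59 CPM (SD, n = 3 each; log2 fold -3.62, SE 0.12, edgeR adjusted p = 2.4e-09). KIF20B, ASPM, CENPF, SGOL2 and CASC5 had log2 folds of -3.25, -3.25, -3.05, -2.88 and -2.75. The other falls were FAM111B (-2.82), PLEKHA7 (-2.71), ZNF488 (-2.68), ANKRD12 (-2.57), AKAP9 (-2.55) and CGB8 (-2.93), of which CGB8 shares reads with near-identical copies and is uncertain. Several of these falls follow coding length and A content, and with that trend removed CENPE was at -0.48, CENPF at -0.59, CASC5 at -0.79 and ANKRD12 at -0.19, while AKAP9 turned to 0.34.

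**Figure D2:**
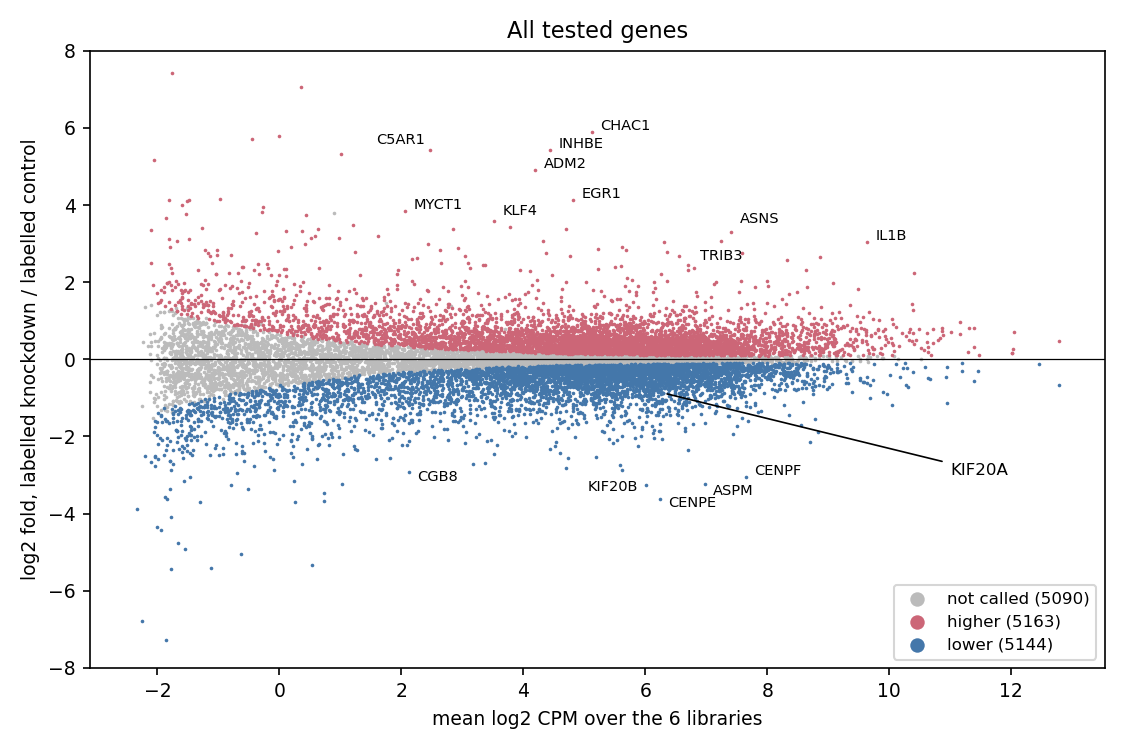
Log2 fold change, labelled knockdown over labelled control, against mean log2 CPM for the 15397 tested genes, 1 point per gene, coloured by edgeR's call at an adjusted p under 0.05. Higher (5163) and lower (5144) genes are about equal in number, and KIF20A lies among many lower genes.

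Of 32 gene lists fixed before the data were examined, 31 had enough tested members. The camera test, with a preset correlation between genes, called 9 higher and 5 lower at an adjusted p under 0.05, of which 7 held with an estimated correlation: the ATF4, AP-1, NF-kB, p53, ribosomal protein, mitosis and kinesin lists. Where counts of changed members adjusted over the list alone differ from those adjusted over all genes tested, both are given.

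Genes of amino acid supply and serine synthesis that ATF4 drives rose together. All 30 members were higher, 28 of them by 2-fold or more, with a median log2 fold of 1.94 (camera adjusted p = 1.3e-115). CHAC1, ASNS and TRIB3 led this list. The endoplasmic reticulum stress list was not called as a set (adjusted p = 0.15), and its median (-0.09) and mean (0.20) differ in sign. It held 7 higher, 12 lower and 4 uncalled members of 23. The higher ones included PPP1R15A (6.75-fold), a phosphatase subunit that restores translation, the transcription factor gene XBP1 (3.08-fold) and HERPUD1 (2.38-fold).

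Genes of cell division fell. In the mitosis and cytokinesis list 39 of 40 members were lower, 19 of them by 2-fold or more, with a median log2 fold of -0.89 (camera adjusted p = 9.1e-37). DLGAP5 fell to 32.6 ± 2.45 from 118 ± 2.06 CPM (SD, n = 3 each), and ANLN, a scaffold gene of the cleavage furrow, had a log2 fold of -1.74. KIF20A fell by about as much as a typical member, since 21 of the 40 had a lower log2 fold. In the list of kinesins other than KIF20A, which also holds transport kinesins such as KIF5B and KIF1B, 18 of 20 were lower and 2 uncalled (adjusted p = 3.0e-15), among them KIF14 (-2.09), KIF11 (-1.65) and KIF18B (-1.27). With the coding length and A content trend removed, 13 kinesins were lower and 4 higher, with KIF14 at -0.84 and KIF11 at -0.93. DNA replication genes were lower in 32 of 40 cases, or 33 adjusted over the list alone, and higher in none, with CLSPN at -1.51, ORC1 at -1.29 and POLE at -1.08. With that trend removed CLSPN was at -0.69, ORC1 at -1.19 and POLE at -0.38. The replication list was called by camera (adjusted p = 1.1e-07) but not with an estimated correlation (adjusted p = 0.23, the highest over the alternatives, against 8.4e-11 as the lowest). Of 30 p53 target genes 21 rose and 2 fell (median log2 fold 0.40, adjusted p = 8.2e-08), led by GDF15 (6.34-fold), SESN2 (5.16-fold) and GADD45A (2.95-fold), genes that other stress pathways also induce. The median of this list was 0.22 with the coding length and A content trend removed, and it was still called. SESN2 is also a member of the ATF4 list. Among apoptosis regulators 18 of 33 rose and 8 fell (adjusted p = 0.0047). This call was lost with an estimated correlation (adjusted p = 0.087) and with the coding length and A content trend removed (adjusted p = 0.14), within 0.0015 to 0.14 over the camera alternatives. MCL1 and BCL2L1, which restrain cell death, rose 1.88-fold and 2.10-fold, and PMAIP1, which promotes it, 3.38-fold.

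The lists of PI3K-AKT signalling, the pathway named in the title, were not called as sets by camera. Fry, which called 29 lists, called the core list lower (adjusted p = 9.0e-06). It called the growth factor and integrin lists higher (fry adjusted p = 0.00026 and 0.015). These lists give mRNA levels of pathway members, and activity of the pathway was not measured. Of 45 core pathway genes 22 were lower, 13 higher and 10 uncalled (median log2 fold -0.15, camera adjusted p = 0.18). MTOR had a log2 fold of -0.90, while EIF4EBP1, whose product represses translation initiation, rose 2.29-fold and RPS6, a ribosomal protein gene, 1.46-fold. With the trend on coding length and A content removed, MTOR was at -0.06 (adjusted p = 0.25). Of 50 growth factors and receptors that feed the pathway 21 were higher and 16 lower (adjusted p = 0.41), with HBEGF up 3.38-fold, EPHA2 2.05-fold and VEGFA 2.04-fold. Of 44 integrins and matrix ligands 17 were higher and 15 lower (adjusted p = 0.60). LAMB3 rose 2.65-fold and THBS2 1.85-fold, and COL4A1 fell by 0.90 on the log2 scale. With that trend removed this list was called higher (adjusted p = 3.3e-05, the lowest over the alternatives, against 0.71 as the highest). FOXO target genes, which AKT restrains, were higher in 11 and lower in 5 of 21 (adjusted p = 0.079), with TXNIP up 2.54-fold and SESN3 at -1.58. Hypoxia and glycolysis genes were higher in 19 and lower in 10 of 33 (adjusted p = 0.079). VEGFA, also on this list, rose 2.04-fold, while PFKFB4 was at -1.11 and ERO1A at -0.76. Without knockdown replicate 3 both of these lists were called higher, FOXO at an adjusted p of 0.043 (0.017 to 0.43 over the camera alternatives) and hypoxia at 0.027 (0.027 to 0.54). With the GC and length trend removed the FOXO and integrin lists were called higher (adjusted p = 0.017 and 0.029), while the collagen and oxidative phosphorylation lists were lost (adjusted p = 0.25 and 0.22).

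Inflammatory and immediate early genes rose. Of 29 NF-kB and inflammatory genes 21 were higher and 3 lower (median log2 fold 0.80, camera adjusted p = 1.9e-10). The cytokine gene IL1B rose 8.23-fold, from 172 ± 4.81 to 1419 ± 24.0 CPM (SD, n = 3 each), the NF-kB subunit gene RELB 4.02-fold and the pentraxin gene PTX3 3.71-fold. Of 32 AP-1 and immediate early genes 27 were higher and 3 lower (median 0.83, adjusted p = 1.7e-24), among them DUSP5 (6.41-fold), CYR61 (4.98-fold) and MYC (3.43-fold). YAP and SRF targets were higher in 20 and lower in 7 of 33, or 8 lower adjusted over the list alone (adjusted p = 4.1e-07, but 0.18 as the adjusted p with an estimated correlation, the highest over the alternatives, against 2.4e-09). ANKRD1 rose 6.83-fold, and CTGF went from 56.8 to 228 CPM. TGF-beta targets went both ways, 15 higher and 12 lower of 28 (adjusted p = 0.79), and their median (0.14) and mean (-0.04) differ in sign. ID1 fell by 1.48 on the log2 scale. Interferon genes were higher in 18 and lower in 11 of 39, or 13 lower adjusted over the list alone (adjusted p = 0.14), with IRF1 up 1.98-fold, IFITM3 1.63-fold and SAMD9 at -2.44. With the coding length and A content trend removed SAMD9 was at -1.25, and IFITM3 went from a log2 fold of 0.70 to 0.36.

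Cholesterol synthesis genes fell, while ribosomal protein genes rose. Of 23 cholesterol genes 20 were lower and 2 higher (median log2 fold -0.60, camera adjusted p = 1.7e-09), with HMGCS1 at -1.99, IDI1 at -1.56 and LSS at -1.43. This call was lost with an estimated correlation (adjusted p = 0.087, the highest over the alternatives, against 1.6e-15 as the lowest). All 74 cytosolic ribosomal protein genes were higher, 8 of them by 2-fold or more (median log2 fold 0.75, adjusted p = 7.9e-38), and their share of all counts was 3.25% to 3.27% in the controls and 5.01% to 5.26% in the knockdown libraries. RPL13A rose 2.11-fold, RPS19 1.95-fold and RPS15A 1.89-fold. These genes have many processed pseudogenes, so single values are uncertain. Nuclear genes of oxidative phosphorylation were higher in 42 and lower in 3 of 55 (median 0.32, adjusted p = 2.8e-05), with NDUFA3, COX7C and COX5B up 1.98-fold, 1.75-fold and 1.73-fold. That call was lost with an estimated correlation (adjusted p = 0.091) and with the coding length and A content trend removed (adjusted p = 0.55, the highest over the alternatives, against 8.2e-07 as the lowest).

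Matrix genes were mixed. Collagens and matrix proteins were lower in 11 and higher in 5 of 26 (median log2 fold -0.13, camera adjusted p = 0.025), with COL7A1 at -1.61, COL5A1 at -1.11 and COL12A1 at -0.86. The call did not hold with an estimated correlation (adjusted p = 0.31), without knockdown replicate 1 (adjusted p = 0.077) or with the coding length and A content trend removed (adjusted p = 0.92, the highest over the camera alternatives, against 0.014). In that last setting COL12A1 was at 0.46. Matrix proteases and inhibitors were higher in 14 and lower in 9 of 30 (adjusted p = 0.011, but an adjusted p of 0.17 with an estimated correlation, within 0.0018 to 0.17 over the camera alternatives). The plasminogen activator genes PLAT and PLAU rose 4.74-fold and 2.34-fold. The list of mesenchymal and epithelial transition factors held 13 higher and 4 lower members of 23 (camera adjusted p = 0.30). Adjusted over the list alone, 6 were lower. ACTA2 rose 3.25-fold and CD44 1.58-fold, while TCF4 was at -1.63.

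The remaining lists were not called by camera. Golgi and RAB6 traffic genes were higher in 11 and lower in 15 of 45 (adjusted p = 0.20), with the long coiled-coil golgin genes GOLGB1, GCC2 and TMF1 at -1.68, -1.49 and -1.25. With the coding length and A content trend removed the balance turned to 24 higher and 9 lower, GOLGB1 to 0.80 and GCC2 to 0.59, and the list was still not called (adjusted p = 0.14, the lowest over the camera alternatives, against 0.50). Replication-dependent histone genes were higher in 4 and lower in 1 of 17 (adjusted p = 0.54), HIST1H1C, HIST1H2AC and HIST1H2BK among the higher, and long non-coding RNAs were higher in 8 and lower in 5 of 14 (adjusted p = 0.079), with SNHG8 up 3.17-fold, ZFAS1 2.29-fold and KCNQ1OT1 at -1.73. Markers of other cell types went both ways. Epithelial markers were higher in 6 and lower in 2 of 14 (adjusted p = 0.71), endothelial in 5 and 1 of 9 (adjusted p = 0.23), blood in 3 and 3 of 7, or 3 and 4 adjusted over the list alone (adjusted p = 0.44), muscle and bone in 3 and 4 of 13 (adjusted p = 0.71) and neural in 1 and 3 of 11 (adjusted p = 0.44). Of these, CD68 and LCP1 rose 1.55-fold and 2.06-fold, ROBO4 2.10-fold, SOX9 1.77-fold and JUP 1.46-fold, while CORO1A was at -0.92, MUC1 at -1.11 and TUBB3 at -0.60. The list of 13 mitochondrially encoded genes had 0 members in the count files and was not tested.

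**Figure D3:**
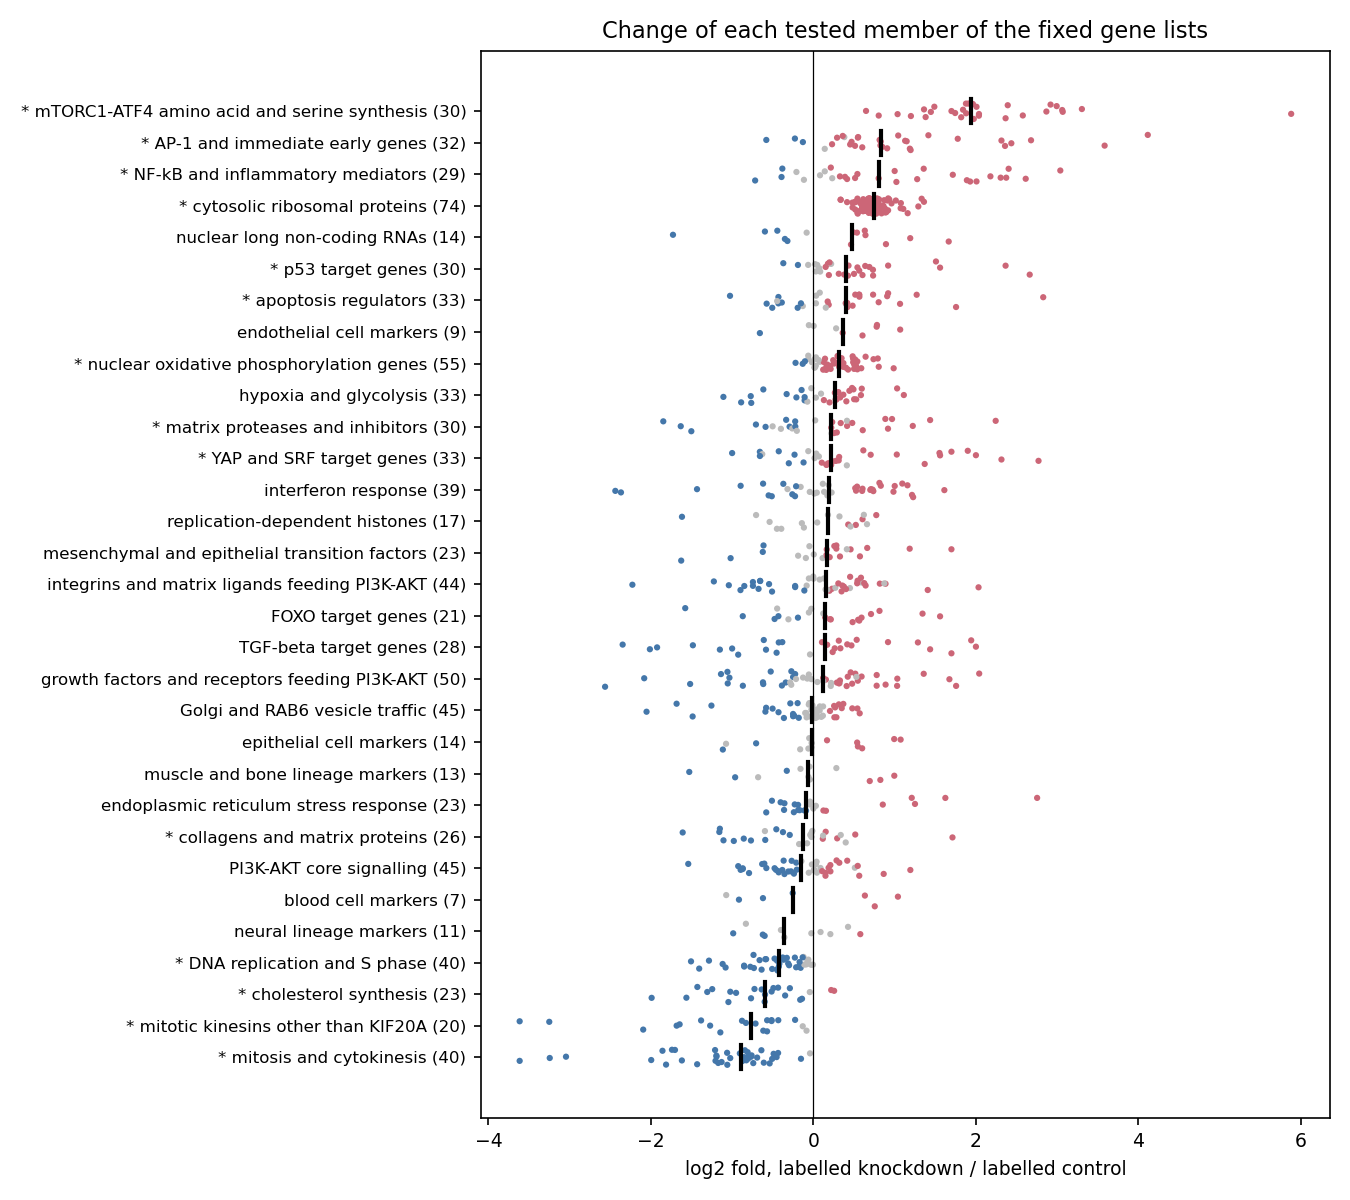
Log2 fold change, labelled knockdown over labelled control, of each tested member (1 point each, number tested in brackets) of the 31 tested gene lists, red for higher, blue for lower and grey for uncalled, with a black bar at the list's median; lists called by camera carry an asterisk, and 1 member of the muscle and bone list with no counts in the knockdown libraries is left out. All 30 ATF4 genes and all 74 ribosomal protein genes lie to the right of 0, and 39 of 40 mitosis genes were called lower.

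Changes across genes followed the length and base content of the coding sequence. Over 9661 genes with a mean log2 CPM above 3, the Spearman correlation of the log2 fold with coding length was -0.40 and with the share of A in the coding sequence -0.30, where genes are not independent replicates. Genes with a coding sequence of 4.5 kb or more and at least 34% A had a median log2 fold of -1.68, and all 53 of them (100%) lay below 0. Those under 1 kb and under 22% A had a median of 0.33, with 21.1% below 0. Within the kinesin and mitosis lists together the log2 folds correlated with A content at -0.69 over 56 genes. With the trend removed, an alternative chosen after the data were seen, KIF20B was at -1.11, ASPM at -0.98 and SGOL2 at -1.37. The median of the kinesin list went to -0.37, that of the mitosis list to -0.78 with all 40 members lower, that of the ribosomal protein list to 0.51 (0.46 with the GC and length trend removed instead) and that of the ATF4 list to 1.86. KIF20A was at -0.74.

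**Figure D4:**
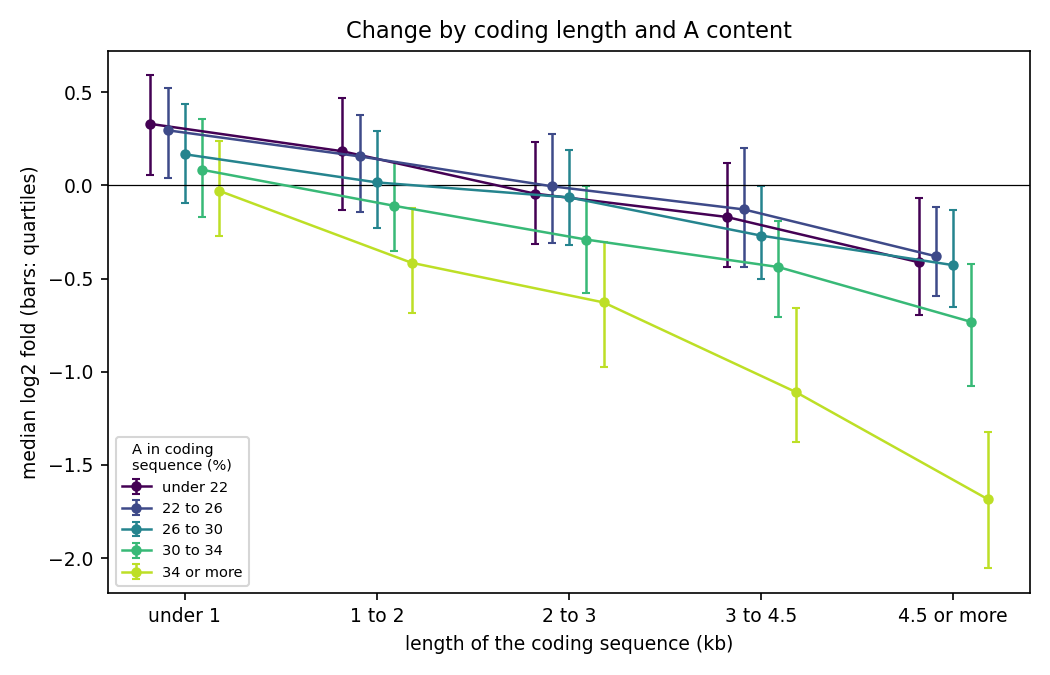
Median log2 fold change, labelled knockdown over labelled control, with quartiles as bars, of genes binned by the length of the coding sequence (kb) and by its share of A (%, 1 line per bin). Medians fall from left to right in every A bin, to -1.68 for the longest sequences with at least 34% A.

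The authors' deposited expression table holds log2-scale values for 20715 genes in the 6 samples and no p-values. KIF20A was at 12.48 ± 0.03 (SD, n = 3) in the controls and 11.86 ± 0.02 (SD, n = 3) in the knockdown libraries of that table, a difference of -0.62. The values match a variance-stabilizing transformation, which compresses folds toward its floor, here 9.61. All 10295 genes called from the counts and found by name in the table differed in the same direction there. Since the table is a transformation of the same counts, this follows almost of itself and gives no independent support.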

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

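The removals of the 2 composition trends were the alternatives chosen after the data were seen, and the deposited table holds no p-values for its threshold alternative. Over the 18 alternatives the log2 fold of KIF20A lay between -0.95 and -0.74, with adjusted p from 1.3e-61 to 4.5e-12. The count of changed genes stayed within 1.5 times of 10307 under all alternatives run, from 8904 at a threshold of 0.01 to 10427 with the replicate number as a block. A similar count did not mean the same genes. With the coding length and A content trend removed, 10141 genes were called. Of these, 8816 were also among the 10307, and 8331 of the shared genes kept their direction. With the GC and length trend removed, 8909 were shared and 8620 of them kept their direction. With libraries scaled by total counts alone, 57.7% of calls were lower, against 49.9%. Leaving out 1 library at a time gave 9519 to 10357 changed genes (4768 to 5254 higher, 4751 to 5103 lower), 1739 to 1879 of 2-fold or more, 2286 to 2604 past the 1.5-fold range and a KIF20A log2 fold of -0.89 to -0.85. The count past a fold range was 6474 against 1.2-fold and 715 against 2-fold, as the range itself sets it.

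The labels state no pairing by replicate number, and the values do not settle whether there was one. Deviations from the group means correlated at 0.13, 0.27 and -0.08 between same-numbered libraries over 10328 genes, and not every library correlated best with its own number. With 3 libraries per group such deviations depend on each other, so these correlations cannot exclude a pairing. With the replicate block, 10427 genes changed, 2570 passed the 1.5-fold range, 1786 had 2-fold or more, 14 lists were called and KIF20A was at -0.87.

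Of the gene lists, 14 were called by camera with the preset correlation, 7 with an estimated correlation and 29 by fry in 1 direction (31 in either direction), since camera compares a list with other genes and fry does not. Without 1 library 13 to 16 lists were called. Without knockdown replicate 1 the collagen list was lost (adjusted p = 0.077), and without knockdown replicate 3 the FOXO and hypoxia lists were gained (adjusted p = 0.043 and 0.027). Without the count filter FOXO, hypoxia and long non-coding RNA lists were gained (adjusted p = 0.042, 0.035 and 0.033).

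Of 110 named genes, 5 changed sign, all with the coding length and A content trend removed, namely AKAP9 (0.34), COL12A1 (0.46), GCC2 (0.59), GOLGB1 (0.80) and MAP2 (0.52). The cause was not tested. In 3 cases a call was lost with its direction kept, MTOR with that trend removed and HIST1H2BK and MAP2 with the GC and length trend removed. The other 1950 values kept direction and side of the threshold.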

Other observations

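The tests of KIF20A, of the long, A-rich coding sequences, of the trend in the ATF4 and mitosis lists and of endoplasmic reticulum stress and day, with all gene lists and genes of this part, were chosen only after the results they weigh were seen. Heat shock genes, mostly cytosolic, were lower in the libraries labelled knockdown, 14 of 18 with 1 higher and 3 uncalled (median log2 fold -0.50, camera adjusted p = 9.2e-09, but an adjusted p of 0.066 with an estimated correlation). The lower ones included HSPD1 (-0.51) and HSPE1 (-0.43), which encode mitochondrial chaperonins. HSPA8, the constitutive HSP70 chaperone gene, fell from 2695 ± 54.5 to 1230 ± 55.5 CPM (SD, n = 3 each), HSP90AA1 had a log2 fold of -1.19 and HSPH1 of -1.21. HSPA1A (-1.75) and HSPA1B (-1.70) are near-identical copies and uncertain singly. BMP-responsive genes, the inhibitors of DNA binding among them, were lower in 8 and higher in 3 of 11 (median -1.48, adjusted p = 3.1e-05, and adjusted p = 0.033 with an estimated correlation). ID3 was at -2.35 (SE 0.062), ID2 at -2.01, SMAD6 at -1.92 and SMAD9 at -1.29, while NOG, which encodes a BMP antagonist, rose 2.25-fold. ID1, ID2, ID3, SMAD6 and others, 6 of the 12 listed, were also on the TGF-beta list.

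The first pattern is the level of KIF20A against the headers. If the labels of the groups were exchanged and the hairpin lowered KIF20A mRNA, KIF20A would be higher in the libraries labelled knockdown, but its log2 fold was -0.87 (SE 0.051). What stays open is why it fell, since KIF20A stood at percentile 52.5 of the mitosis list. A direct effect of a hairpin and the shared fall of mitosis genes cannot be told apart on these values, and with the shared fall the level of KIF20A would say nothing of which construct a library carried.

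The second pattern is the fall of genes with long, A-rich coding sequences. GC content alone correlated with the log2 fold at 0.29, about as strongly as coding A (-0.30), and coding T at -0.16, but in the joint regression the effect per percent of coding T was 0.010 of that per percent of coding A (-7.31 standard errors from 0.5), which argues against a GC bias as the whole cause. RNA degradation before poly(A) selection, which no label states, should act on 3' UTR length as on coding length, but the effect per kb of 3' UTR was 0.30 of that per kb of coding sequence (-5.47 standard errors from 0.5). Priming at A-rich stretches should act on A in the 3' UTR, which alone correlated at -0.20, but whose joint effect was -0.065 of that of coding A (-9.42 standard errors from 0.5). Both 3' UTR ratios rest on the annotated transcript with the longest coding sequence, and the 3' UTRs used in these cells were not measured. An error in them would lower the ratios, so degradation and priming cannot be excluded. All these standard errors treat genes as independent. Removal of the trend left 96.0% of the median log2 fold for ATF4 targets, 87.6% for mitosis genes and 68.3% for ribosomal protein genes (median 0.46 with the GC and length trend removed), but took the medians of kinesins from -0.77 to -0.37, p53 targets from 0.40 to 0.22, apoptosis regulators from 0.40 to 0.10 and oxidative phosphorylation genes from 0.32 to 0.04, and no biological explanation of the trend was tested.

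The third pattern is the rise of ATF4 targets. Endoplasmic reticulum stress stays open, since its ATF6 and XBP1 targets, chaperone genes and others, went both ways. Of 20, 25% were higher and 11 lower (median log2 fold -0.10, camera adjusted p = 0.40), and 17 were already on fixed lists. The 5 higher ones were DNAJB9, PDIA3, SEC61B, SPCS2 and SRPRB, of which SEC61B, SPCS2 and SRPRB do not encode chaperones. The chaperone genes HSPA5 and HSP90B1 were at -0.23 and -0.51, while DNAJB9 rose 1.81-fold, PDIA3 1.11-fold and SRPRB 1.27-fold. Outside this list XBP1 rose 3.08-fold and HERPUD1 2.38-fold. A difference of day, culture or processing between the groups stays open too, as 0 folders held libraries of both groups, and it cannot be told apart from an effect of the knockdown.

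Of 20 cytosolic aminoacyl-tRNA synthetase genes 14 were higher (70%), 3 lower and 3 uncalled (camera adjusted p = 7.7e-14). GARS and SARS rose 3.68-fold and 3.76-fold, and 5 of the 20 are ATF4 list members. Of 17 mitochondrial ones 9 were higher (52.9%), 5 lower and 3 uncalled, and the set was not called (camera adjusted p = 0.78). Whether synthetase genes rose in general stays open.

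Lower mTORC1 activity with activation of TFEB is a hypothesis for the fall of cholesterol genes. It needs lysosome genes, which TFEB drives, to be higher, and 85.7% of 28 were (24 higher, 2 lower, median log2 fold 0.56, camera adjusted p = 4.1e-09, but an adjusted p of 0.066 with an estimated correlation). PSAP rose 2.06-fold, TPP1 1.92-fold and CTSD 1.82-fold. Other causes of a rise in lysosome genes were not tested, and protein activity was not measured.

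Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 10307 genes in edgeR's test. The highest other split gave 0 genes at an adjusted p under 0.05 and at most 114 at an unadjusted p under 0.05. Each other split mixes libraries of both groups on both sides, so the difference between the groups adds to the spread within sides. Few calls follow from this mixing, and these counts do not show what chance alone gives. With 10 splits a share under 0.05 cannot be reached.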
